A study of Homo sapiens with 12 samples.

How the data were processed

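RNA from SH-SY5Y cells, a human neuroblastoma line, was measured by sequencing in 12 libraries. Per the labels, the cells were wild type (control), overexpressed ADAR2 (ADAR2 OE), carried a knockdown of SRSF9 (SRSF9 KD), or combined both (ADAR2 OE + SRSF9 KD). Each of the 4 groups held 3 libraries. The series title speaks of SRSF9 overexpression where the sample labels speak of a knockdown; the groups follow the sample labels, and SRSF9 counts were lower in both groups labelled as a knockdown. Per the labels, RNA was taken up in Trizol and 2 ug of it went into each library, made with the NEBNext Ultra Directional kit. How the overexpression and the knockdown were made, and whether the replicates were separate cultures, is not given in the sources used here, so the p-values measure the spread between these libraries.

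The deposited table holds the authors' raw read count for each of 57268 annotated genes in each library, with versioned Ensembl gene IDs and gene symbols. The submitters' processing notes name STAR, Picard, GATK, SAMtools and the hg19 build, without roles or versions. The program that made the counts, its strand setting and the annotation release are not given in the sources used here. Between 63.8% and 67.7% of the counts from 1 to 12 were even numbers, so both ends of a read pair probably entered many counts, and counting error is understated to that extent. Intervals and lower bounds in the text cover counting error only. Gene positions are not given because the annotation used here is on GRCh38 and the counts on hg19. Gene symbols are those of the table; 51465 of the 57268 IDs also matched the newer name table used here. RNA editing itself was not analysed here: the counts carry no base calls, and for ADARB1 they do not separate an introduced copy from the gene in the genome.

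Library totals ran from 43.5 to 91.4 in megacounts. Genes were tested when they passed edgeR's filterByExpr by group, which left 23824. Counts were scaled by TMM, with factors between 0.956 and 1.04, and 1 edgeR quasi-likelihood fit with robust dispersion took in all 12 libraries, so that the groups of 3 shared an estimate of the spread (common biological coefficient of variation 0.23). Levels are CPM, counts per megacount on TMM-scaled totals, given as mean and SD over 3 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 23824 genes, with no minimum fold. The 6 comparisons were ADAR2 OE with control, SRSF9 KD with control, the combined group with each of the other 3, and the interaction, which is the SRSF9 knockdown effect with ADAR2 overexpression minus that without it. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0.

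The groups, the comparisons, the tests, the gene lists, the rule for named genes and all alternatives other than the surrogate variable and 1 blocked fit were fixed before the data were examined. The rule named ADARB1 and SRSF9 in every comparison. For ADAR2 OE with control, SRSF9 KD with control, and the combined group with ADAR2 OE, it took called genes with a symbol other than a clone or pseudogene name, a mean of at least 8 CPM over the 12 libraries, and all 3 libraries of one group beyond all 3 of the other. Of these it named up to 10 per direction by fold change. The same rule took up to 4 per direction for the other comparisons with the combined group. For the interaction it took up to 5 per direction among called genes of at least 8 CPM. From each gene list it named up to 4 members with the smallest adjusted p. Counts of named genes or rule genes within a comparison leave out those named only from a list. Other genes in the text are said to be chosen after their values were seen. For SRSF9 KD with control, 1 gene that the rule named is not reported here, though the counts include it. Between 6 and 26 of the called genes per comparison had a mean under 8 CPM.

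The 24 gene lists covered A-to-I editing enzymes and their regulators, reported ADAR2 substrates, SR proteins, hnRNPs, kinases and importers of SR proteins, interferon-stimulated genes, double-stranded RNA sensors, integrated stress response targets, endoplasmic reticulum chaperones, heat shock proteins, p53 targets, cell cycle genes, histones, noradrenergic identity genes, mesenchymal (S-type) markers, glial markers, epithelial markers, neuronal genes, immediate early genes, cholesterol genes, glycolysis and hypoxia genes, mitochondrial mRNAs, ribosomal proteins, and small nuclear and nucleolar host transcripts. For each list the members called over all genes and those past an adjusted p of 0.05 adjusted over the list alone were counted. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the 24 lists of a comparison.

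The tests were tried on simulated counts, drawn from a negative binomial distribution with the mean level and dispersion of each gene and the depth of each library, with known folds put into genes of at least 1 CPM. At a true fold of 2, between 26.9% (interaction) and 68.7% (combined group with ADAR2 OE) of changed genes were recovered. At a true fold of 4 the lowest share was 78.8%, again for the interaction. False calls made up 5.3% to 8.9% of calls.

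Alternatives were RLE scaling, library totals alone, DESeq2, limma-voom, no low-count filter, a filter of at least 5 CPM in at least 3 libraries, a minimum log2 fold change of 1, replicate number as a block, a term for replicate 3, fits to only the groups compared, and fits without each library in turn. A fit with 1 surrogate variable from sva was added and was chosen after seeing the data. Each comparison's count was also taken over other splits of the same libraries. For the genes shared between comparisons that use the same control libraries, 20 simulations drew the 3 altered groups with no change, around a mean that differed from the control mean only by its sampling error, and tested them against the real control libraries. These called at most 1 gene in a comparison, so they serve for the covariance and correlation of fold changes and not for the number of genes shared. They drew each gene on its own, so they hold no variance common to many genes in the altered groups. Genes that differed between any of the 4 groups were also sorted by the group or pair of groups whose mean log2 CPM stood apart, with all 12 libraries and with each replicate number left out in turn. Scoring the left-out libraries took the place of an earlier test, in which 48 of 49 genes had all 3 libraries of the group beyond the 9 others, because the choice of genes had favoured that outcome; its limits were set after the earlier result was known. In the same way, SMG1 was first set against 0.5 times the median change of its copies, a limit with no ground in how shared reads act, and then against each copy. The comparisons used all 12 libraries. The summed CPM of each list was also set against the sides of the first principal component, after that component was seen; 6 of the 24 lists, immediate early genes among them, had no overlap between the sides.

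The labels give the groups the same replicate numbers without saying what a number stands for. Same-number libraries of the combined group and control deviated together from their group means, with correlations across genes of 0.36, 0.45 and 0.24, all above 0.1, so the numbers were taken as pairs in that comparison. The pairing comes from the counts, and the counts of genes with the block were known when it was taken up. The fit without the block stays the main one, as fixed, and blocked values stand beside results they change. A blocked fit to these 6 libraries alone was added and chosen after seeing the data.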

Results

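Gene expression was measured by RNA sequencing in 12 libraries of SH-SY5Y cells, a human neuroblastoma line, in 4 groups of 3. The groups were control, ADAR2 overexpression (ADAR2 OE), SRSF9 knockdown (SRSF9 KD), and both together (the combined group). ADAR2 is an enzyme that edits adenosine to inosine in RNA, and SRSF9 is a splicing factor of the SR family. The series states as its subject the effect of SRSF9 on editing at ADAR2 sites; editing was not analysed here, and the comparisons below are of transcript levels. In the order of replicates 1 to 3 and in megacounts, the libraries held 64.9, 58.7 and 72.3 in control and 68.5, 68.9 and 43.5 in ADAR2 OE. They held 74.3, 83.7 and 63.1 in SRSF9 KD and 91.4, 47.7 and 80.6 in the combined group.

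The libraries also differed within groups. Immediate early genes, such as FOS and ATF3, which respond within minutes to stimulation or stress, summed to 1059, 2176 and 929 CPM in the control libraries of replicates 1 to 3. They summed to 1806, 1398 and 956 CPM in ADAR2 OE, to 1889, 2026 and 864 CPM in SRSF9 KD, and to 935, 2553 and 929 CPM in the combined group. Within control, FOS alone ran from 5.7 CPM in replicate 3 to 116 CPM in replicate 2. The first principal component, which held 29.6% of the variance, placed replicate 2 of control, replicate 2 of the combined group and replicates 1 and 2 of ADAR2 OE and of SRSF9 KD on one side, and the other 6 libraries on the other. Among the 20 genes with the largest weight toward the side of high immediate early sums, FOSB ranked 11 and FOS ranked 19. Of the 24 tested immediate early genes, 0 were called by edgeR's quasi-likelihood test in any of the 6 comparisons, with at most 2 at an unadjusted p under 0.05 in a comparison and 0 by DESeq2 or limma-voom.

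**Figure D1:**
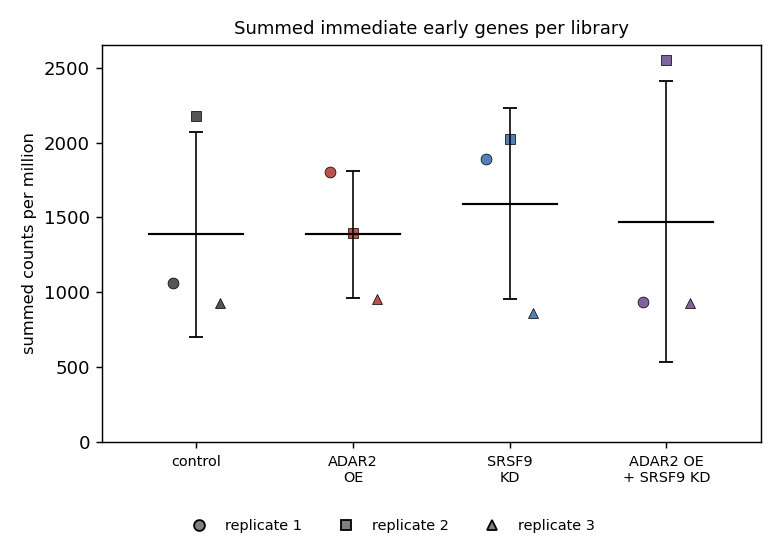
Summed CPM of the immediate early genes in each library, by group; points are libraries, lines are group means and bars are SD (n = 3). The replicate 3 libraries lie between 864 and 956, and the highest library is combined replicate 2 at 2553.

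ADARB1, the gene for ADAR2 (ENSG00000197381.11), stood at 43 ± 1.37 CPM in control and 40.1 ± 3.31 CPM in SRSF9 KD (SD, n = 3). It reached 2140 ± 702 CPM in ADAR2 OE and 1420 ± 501 CPM in the combined group. The rise over control was 5.64 on the log2 scale in ADAR2 OE (SE 0.28, adjusted p = 7.07e-07, edgeR quasi-likelihood with Benjamini-Hochberg) and 5.05 in the combined group (adjusted p = 1.02e-06). Between the combined group and ADAR2 OE, ADARB1 had a log2 fold change of -0.59 (SE 0.23, adjusted p = 0.575), which did not pass the edgeR test. Adjusted over the editing enzyme list alone its p was 0.311, and it was 1 of 2 list members at an unadjusted p under 0.05. Equal ADARB1 levels in these groups are therefore not shown. SRSF9 (ENSG00000111786.4) stood at 282 ± 34.2 CPM in control and 257 ± 33.5 CPM in ADAR2 OE. It was at 81.3 ± 5.75 CPM in SRSF9 KD and 81.8 ± 9.32 CPM in the combined group. SRSF9 fell by 1.80 on the log2 scale in SRSF9 KD against control (SE 0.13, adjusted p = 3.32e-05) and fell by 1.65 in the combined group against ADAR2 OE (SE 0.13, adjusted p = 9.01e-05). ADARB1 did not pass the test in SRSF9 KD against control (log2 fold change -0.10, adjusted p = 0.989), nor SRSF9 in ADAR2 OE against control (-0.14, adjusted p = 1).

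**Figure D2:**
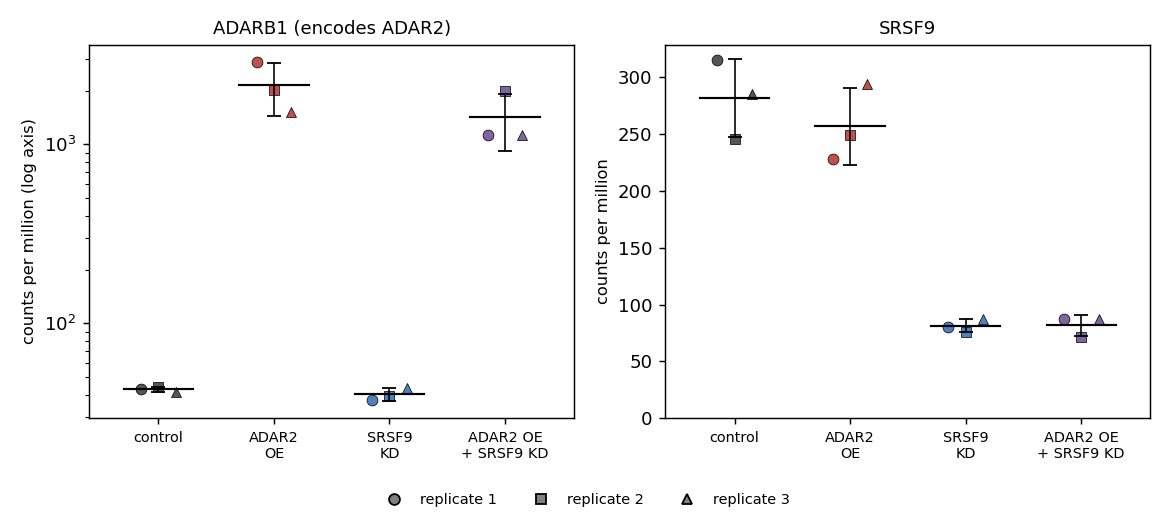
CPM of ADARB1 (left, log axis) and SRSF9 (right) in each library, by group; points are libraries, lines are group means and bars are SD (n = 3). ADARB1 averages 2140 in ADAR2 OE and 1420 in the combined group against 43 in control, and SRSF9 averages 81.3 and 81.8 in the groups labelled as a knockdown against 282 in control.

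The comparison of ADAR2 OE with control asked what extra ADAR2 changed against cells labelled wild type. The sources used here do not say whether the control was handled like the altered cells. In comparisons with control, an effect of the manipulation itself is therefore not told apart from one of ADAR2 or SRSF9. Apart from ADARB1, ABCA3, a lipid transporter, rose most among the genes the rule named, from 37.5 ± 5.19 to 372 ± 100 CPM (SD, n = 3; log2 fold change 3.31, SE 0.24, adjusted p = 1.83e-05). SLC7A11, a subunit of the cystine/glutamate exchanger and a target of the transcription factor ATF4, rose from 7.94 ± 1.19 to 22.6 ± 4.51 CPM (log2 fold change 1.51, adjusted p = 0.0032). LNPEP, the insulin-regulated aminopeptidase, fell from 222 ± 47.5 to 28.1 ± 8.86 CPM (log2 fold change -2.98, SE 0.24, adjusted p = 3.66e-05). ZDHHC17, a palmitoyltransferase, fell by 1.01 on the log2 scale (adjusted p = 0.0309), and NDUFS7, a subunit of respiratory complex I, fell by 0.75 (adjusted p = 0.0151). In all, 21 genes were called, 12 higher and 9 lower. Among the 12 higher genes, several with low counts in control were chosen after their values were seen. POF1B, which encodes an actin-binding protein, went from 0.154 ± 0.0818 to 10.8 ± 2.81 CPM, APOBEC3G, a cytidine deaminase, from 0.385 ± 0.165 to 9.30 ± 2.64 CPM, and MEIOB, a meiosis gene, from 0.0838 ± 0.0241 to 4.22 ± 0.762 CPM. SYT1, the calcium sensor of synaptic vesicles, which the rule named only from the neuronal list, rose by 2.15 on the log2 scale (adjusted p = 0.00767). The count fell from 21 to 13 without control replicate 2, without ADAR2 OE replicate 2 or without ADAR2 OE replicate 3, and DESeq2 called 51 genes. Of the 5 named genes other than ADARB1, ABCA3, LNPEP and SLC7A11 kept their calls in all 6 fits that left out 1 library, while NDUFS7 and ZDHHC17 each kept it in 1; SYT1 lost its call without control replicate 2 (adjusted p = 0.0698) or control replicate 3 (0.0672).

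By gene list, reported ADAR2 substrates held 25 tested genes, of which 0 were called by edgeR in ADAR2 OE against control, with 0 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom. Of the 20 tested editing enzymes and regulators, ADARB1 alone was called (camera adjusted p = 0.31, and adjusted p = 0.8 with an estimated correlation). Of 38 integrated stress response targets, 37 had a positive log2 fold change, with a median of 0.31. Their summed CPM leaned with the sides of the first component, with some overlap. It was 4194 to 5873 on the side with high immediate early sums, which held 2 libraries of ADAR2 OE and 1 of control, and 3381 to 4535 on the other. An effect of ADAR2 on the list as a whole is not told apart from this imbalance. SLC7A11 was called by edgeR (8 at an unadjusted p under 0.05, 2 by DESeq2), and NUPR1, a stress-induced chromatin protein with a log2 fold change of 2.03, was past the threshold with it when adjusted over the list alone. Camera gave an adjusted p of 8.2e-17 for this list, and adjusted p = 0.62 with an estimated correlation. The 78 ribosomal protein genes all had negative values, with a median of -0.15 and 0 called (5 at an unadjusted p under 0.05, 0 by DESeq2). Camera gave them adjusted p = 6.1e-13, and adjusted p = 0.8 with an estimated correlation. Cholesterol genes had a median of -0.27 (adjusted p = 5e-04, and adjusted p = 0.8 with an estimated correlation). Of 30 mesenchymal markers, SPARC (log2 fold change 0.97) and COL3A1 (1.32), both matrix genes, were past the threshold when adjusted over the list alone (list adjusted p = 0.0032, and adjusted p = 0.8 with an estimated correlation). Over all genes edgeR called 0 of the 30, DESeq2 1 and limma-voom 0. The summed CPM of this list followed the sides of the first component, at 1245 to 1657 in the 6 libraries of the high immediate early side, of which ADAR2 OE held 2 and control 1, and at 1016 to 1125 in the other 6. Camera called 9 of the 24 lists in this comparison, and 0 held with an estimated correlation or by fry's test for change in 1 direction, nor by its test for change in either direction.

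The comparison of SRSF9 KD with control asked what the knockdown changed without extra ADAR2. ZNF687, a zinc finger protein, rose from 81.5 ± 0.448 to 368 ± 81.9 CPM (SD, n = 3; log2 fold change 2.17, SE 0.14, adjusted p = 1.96e-05). LNPEP fell from 222 ± 47.5 to 19.6 ± 3.02 CPM (log2 fold change -3.50, SE 0.24, adjusted p = 1.98e-05). TYMS, which encodes thymidylate synthase, fell from 79.1 ± 5.42 to 25.1 ± 1.51 CPM (log2 fold change -1.66, SE 0.15, adjusted p = 0.000254), and CHUK, the kinase IKK-alpha, fell from 63.2 ± 15.4 to 23.1 ± 3.8 CPM (log2 fold change -1.45, adjusted p = 0.0126). SOX11, a transcription factor of immature neurons, had a mean under the rule's minimum and was named only from the noradrenergic list. It fell from 19.9 ± 6.37 to 1.38 ± 0.481 CPM (log2 fold change -3.84, adjusted p = 3.72e-05).

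The other rule genes moved less. OGDHL, a relative of the 2-oxoglutarate dehydrogenase subunit, PPP1R3F, BEX5, IFI27L2 and the tumour antigen gene PRAME rose by 1.13, 0.91, 0.89, 0.85 and 0.74 on the log2 scale, with adjusted p-values from 0.0126 to 0.0353. ZDHHC17 fell by 1.13, UBR7 fell by 0.80, SDC2, a cell surface proteoglycan, fell by 0.79, BTBD1 fell by 0.78 and ZHX1 fell by 0.76, with adjusted p-values from 0.00983 to 0.0488. In all, 50 genes were called, 23 higher and 27 lower. Of the low-count genes chosen after their values were seen, CLEC4C, a dendritic cell lectin, had 0 counts in control and 1.61 ± 0.363 CPM in SRSF9 KD, at least 103-fold higher than the floor of 3 counts over the control group. RNU6-118P, a U6 pseudogene, had 0 counts in control and was at least 127-fold higher on the same floor. The count of 50 became 29 without control replicate 1, 18 without control replicate 2, 19 without control replicate 3, and 19, 19 and 20 without SRSF9 KD replicates 1, 2 and 3, against 188 by DESeq2. Of the 15 named genes other than SRSF9, LNPEP, TYMS and ZNF687 kept their calls in every fit that left out 1 library, and the other 12 lost theirs in at least 1.

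Of the 17 tested SR proteins, SRSF9 was the only one called in SRSF9 KD against control. The list had a median log2 fold change of -0.16 (camera adjusted p = 4.2e-05, and adjusted p = 0.28 with an estimated correlation). The 24 hnRNP genes all had negative values, with a median of -0.15 and 0 called (2 at an unadjusted p under 0.05, 0 by DESeq2 or limma-voom; camera adjusted p = 7.7e-05, and adjusted p = 0.67 with an estimated correlation). Their summed CPM was 10851 to 12779 in the 6 libraries of the high immediate early side, 2 of them of SRSF9 KD and 1 of control, and 12846 to 15973 in the other 6. Among 40 cell cycle genes, TYMS was called, and the list's median was -0.15 (adjusted p = 5.8e-06, and adjusted p = 0.56 with an estimated correlation). Their summed CPM was 6550 to 7181 on the high immediate early side and 6978 to 7998 on the other. Among 9 epithelial markers 0 were called by edgeR, 4 lay at an unadjusted p under 0.05, and DESeq2 called 3. EPCAM (log2 fold change 1.31), CLDN3 (1.41) and KRT8 (1.10) were past the threshold when adjusted over the list alone (camera adjusted p = 3e-06, and adjusted p = 0.28 with an estimated correlation). Among 30 neuronal genes, SYT1 rose by 1.78 on the log2 scale (adjusted p = 0.0201; 0.132 and 0.136 without control replicates 2 and 3, and 0.0702, 0.111 and 0.0904 without SRSF9 KD replicates 1, 2 and 3), and CACNA1B, a presynaptic calcium channel gene (1.65), joined it when adjusted over the list alone. Over all genes edgeR called 1 of the 30 and DESeq2 2. The list's summed CPM followed the sides of the first component, at 14489 to 17558 on the high immediate early side, with 2 libraries of SRSF9 KD and 1 of control, and 9120 to 12768 on the other. The neuronal list had adjusted p = 4e-06, and adjusted p = 0.48 with an estimated correlation. Markers of other cell types also passed the threshold over their lists alone. These were the glial marker GFAP (log2 fold change 1.15, 2.4 CPM in SRSF9 KD) and the mesenchymal marker PRRX1 (1.55, 1.42 CPM). Over all genes edgeR called 0 of either list and DESeq2 1 of each. SOX11 was the only one of 21 noradrenergic identity genes called, and the list's median, 0.15, had the opposite sign to camera's direction (adjusted p = 0.76, and adjusted p = 0.89 with an estimated correlation). Camera called 8 of the 24 lists, and 0 held with an estimated correlation or by fry's test for change in 1 direction. Fry's test for change in either direction called 4 of the 8: SR proteins (adjusted p = 0.0032), cell cycle genes (0.0069), epithelial markers (0.017) and neuronal genes (0.017). The SR protein list holds SRSF9, altered by design, so its call does not show a change of the other members. In the cell cycle list TYMS alone was past the edgeR threshold adjusted over the list alone (adjusted p = 2.56e-06, with CDK1 next at 0.0714). That list's call therefore does not show a change of its other members either.

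**Figure D3:**
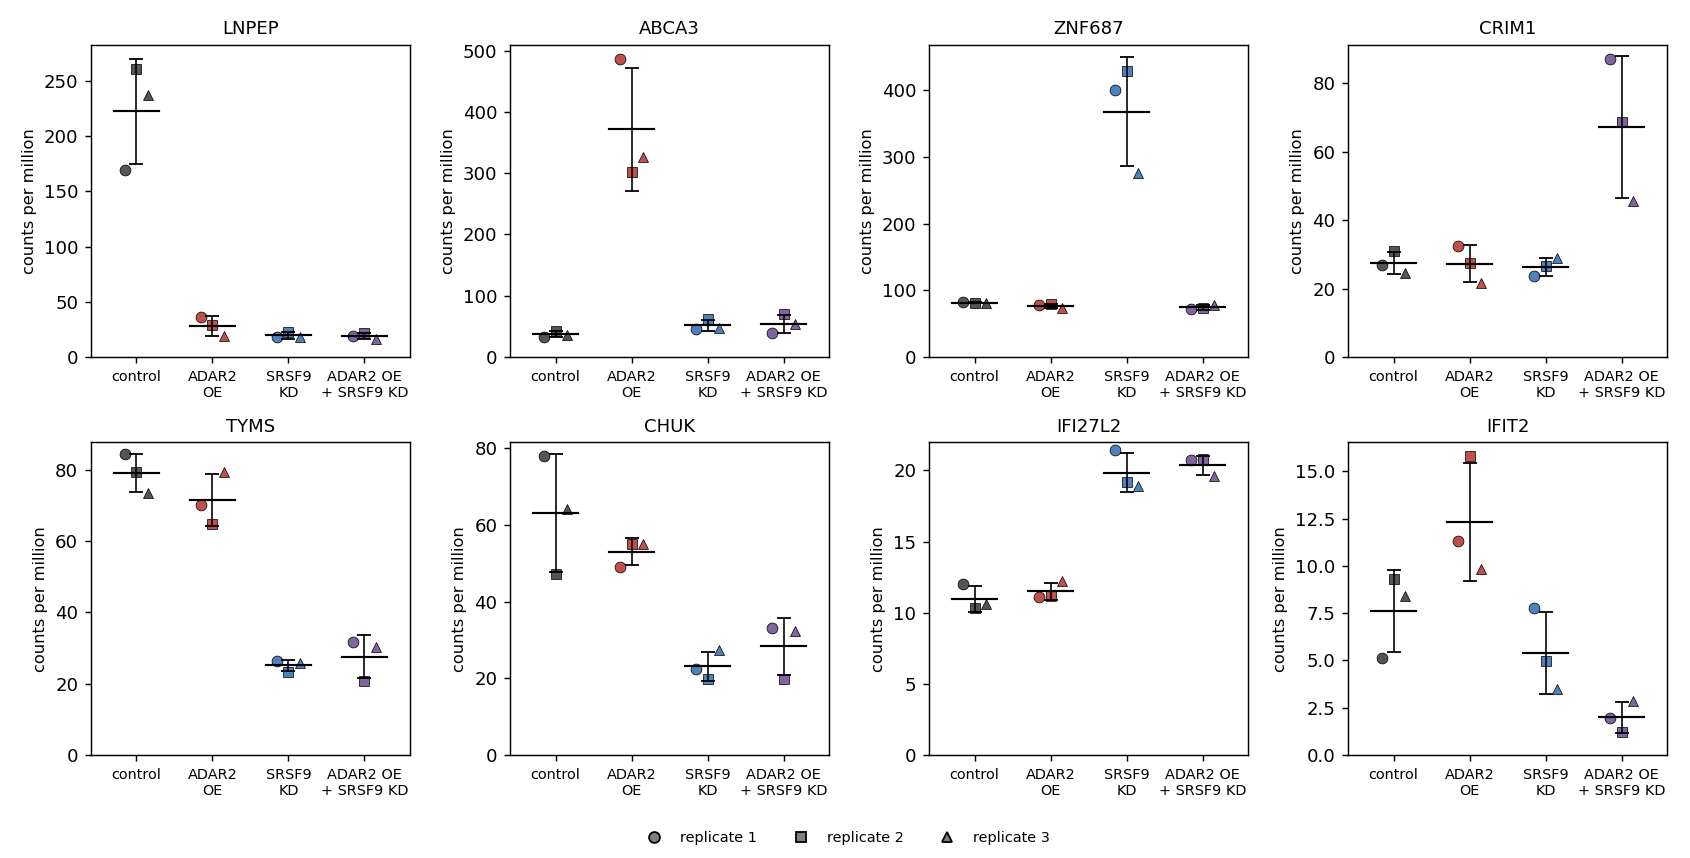
CPM of 8 genes in each library, by group; points are libraries, lines are group means and bars are SD (n = 3). LNPEP is high in control alone (222), ABCA3 in ADAR2 OE alone (372), ZNF687 in SRSF9 KD alone (368) and CRIM1 in the combined group alone (67.2), while TYMS, CHUK and IFI27L2 separate both knockdown groups from the other groups, and IFIT2 is lowest in the combined group (1.99).

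The comparison of the combined group with ADAR2 OE asked what the SRSF9 knockdown changed on top of extra ADAR2, the setting the series names. ABCA3 fell from 372 ± 100 to 54 ± 15.4 CPM (SD, n = 3; log2 fold change -2.78, SE 0.23, adjusted p = 0.000116). TYMS fell from 71.5 ± 7.3 to 27.6 ± 6.05 CPM (log2 fold change -1.37, SE 0.15, adjusted p = 0.00211), and SLC7A11 fell from 22.6 ± 4.51 to 9.48 ± 1.21 CPM (log2 fold change -1.25, adjusted p = 0.0197). CRIM1, a membrane protein that binds bone morphogenetic proteins, rose from 27.3 ± 5.41 to 67.2 ± 20.8 CPM (log2 fold change 1.30, adjusted p = 0.0383). INA, the neuronal filament alpha-internexin, rose from 4.88 ± 0.608 to 11.9 ± 1.91 CPM (log2 fold change 1.29, adjusted p = 0.0428). TCEAL3 rose by 0.94 and IFI27L2 by 0.82 on the log2 scale (adjusted p = 0.0197 and 0.0244), LRIG3 fell by 0.80 (adjusted p = 0.0383), and SFXN1, a mitochondrial serine transporter, fell by 0.76 (adjusted p = 0.0391). In all, 22 genes were called, 4 higher and 18 lower. Named only from their gene lists, IFIT2, an interferon-induced gene, fell from 12.3 ± 3.1 to 1.99 ± 0.819 CPM (adjusted p = 0.0154), and SOX11 fell by 2.06 on the log2 scale (adjusted p = 0.0136). Chosen after their values were seen, POF1B fell by 6.48 (adjusted p = 2e-05) and APOBEC3G fell by 4.38 (adjusted p = 8.7e-05). The count became 7 without combined replicate 1, without ADAR2 OE replicate 1 or without ADAR2 OE replicate 2, 9 without combined replicate 3, 13 without ADAR2 OE replicate 3, 8 in a fit to these 6 libraries alone, and 162 by DESeq2. Of the 9 named genes other than SRSF9, ABCA3 and TYMS kept their calls in every fit that left out 1 library; TYMS had adjusted p = 0.0807 in the fit to these 6 libraries alone, within a range of 1.31e-12 to 0.0807 over its alternatives, and IFIT2 lost its call without combined replicate 1 (adjusted p = 0.114), ADAR2 OE replicate 1 (0.061) or ADAR2 OE replicate 2 (0.113), as SOX11 did without combined replicate 1 (0.0937), combined replicate 3 (0.0992), ADAR2 OE replicate 1 (0.0725) or ADAR2 OE replicate 2 (0.0858).

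Of 39 interferon-stimulated genes, edgeR called IFIT2 alone in the combined group against ADAR2 OE, with 9 at an unadjusted p under 0.05, 5 called by DESeq2 and 1 by limma-voom. IFIT2, OASL, IFIT3, IFI44, IFI35 and IFIT1, all 6 lower, were past the threshold when adjusted over the list alone. IFIT3 went from 8.52 ± 3.01 to 1.81 ± 0.316 CPM and OASL from 4.11 ± 1.47 to 1.02 ± 0.387 CPM. The list had 18 positive and 21 negative members, a median of -0.02 and a mean of -0.45 (camera adjusted p = 0.00046, and adjusted p = 0.75 with an estimated correlation). Fry's test for change in either direction gave adjusted p = 0.0037, and its test for change in 1 direction gave 0.59. IFIH1, a sensor of double-stranded RNA, had a log2 fold change of -1.88 and was the only one of 12 such sensors past the threshold adjusted over the list alone (0 called by edgeR over all genes and 1 by DESeq2; list adjusted p = 0.47, and adjusted p = 0.75 with an estimated correlation). Among 38 integrated stress response targets, SLC7A11 and NUPR1 (log2 fold change -2.10) were past it over the list alone, with a list median of -0.16 (1 called by edgeR over all genes, 2 by DESeq2 and 2 by limma-voom; adjusted p = 3e-04, and adjusted p = 0.75 with an estimated correlation). The high immediate early side, where this list's sums leaned higher, held 2 libraries of ADAR2 OE and 1 of the combined group. Cholesterol genes had a median of 0.38, with 21 of 23 positive and 0 called (6 at an unadjusted p under 0.05, 0 by DESeq2; camera adjusted p = 2.3e-06, and adjusted p = 0.75 with an estimated correlation). Of the 25 tested ADAR2 substrates, 0 were called by edgeR, 0 lay at an unadjusted p under 0.05, and DESeq2 called 0. Camera called 6 of the 24 lists, and 0 held with an estimated correlation or by fry's test for change in 1 direction; the interferon list was the 1 of the 6 called for change in either direction.

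The comparison of the combined group with SRSF9 KD asked what extra ADAR2 changed in knockdown cells. ADARB1 rose by 5.15 on the log2 scale (SE 0.28, adjusted p = 8.41e-07), from 40.1 ± 3.31 to 1420 ± 501 CPM. ZNF687 fell from 368 ± 81.9 to 74.4 ± 3.27 CPM (SD, n = 3; log2 fold change -2.31, SE 0.14, adjusted p = 3.32e-06). These were the rule genes among 8 called, 3 higher and 5 lower. Chosen after their values were seen, MEIOB rose from 0.0397 ± 0.0112 to 11.2 ± 3.51 CPM, and NALCN, a sodium leak channel gene, rose from 0.143 ± 0.0381 to 1.58 ± 0.213 CPM (log2 fold change 3.46, adjusted p = 0.000248). FYB, CLEC4C, RN7SL119P and RNU6-118P were the other lower genes, each under 4 CPM in SRSF9 KD; CLEC4C lost its call without SRSF9 KD replicate 1 (adjusted p = 0.0596), SRSF9 KD replicate 3 (0.0586) or combined replicate 3 (0.0833), and RNU6-118P without SRSF9 KD replicates 1 (0.367) and 2 (0.14) and combined replicates 1 (0.143), 2 (0.144) and 3 (0.423). Among 39 interferon-stimulated genes 0 were called by edgeR, 5 lay at an unadjusted p under 0.05 and DESeq2 called 0. IFIT2 (log2 fold change -1.42), OASL (-1.41) and IFITM2 (-0.58) were past the threshold when adjusted over the list alone (camera adjusted p = 6.4e-05, and adjusted p = 0.61 with an estimated correlation). Of 40 cell cycle genes 37 had positive values, with a median of 0.15 and 0 called (7 at an unadjusted p under 0.05, 0 by DESeq2; camera adjusted p = 1.3e-08, and adjusted p = 0.61 with an estimated correlation). Their summed CPM was 6550 to 7181 on the high immediate early side, with 2 libraries of SRSF9 KD and 1 of the combined group, and 6978 to 7998 on the other. Glycolysis and hypoxia genes had a median of -0.24 (adjusted p = 5.5e-05, and adjusted p = 0.63 with an estimated correlation). Camera called 10 of the 24 lists, and 0 held with an estimated correlation or by fry's test for change in 1 direction; for change in either direction it called 1 of the 10, the editing enzymes, with ADARB1. DESeq2 called 15 genes in this comparison.

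The comparison of the combined group with control took both alterations together. LNPEP fell from 222 ± 47.5 to 19 ± 2.51 CPM (SD, n = 3; log2 fold change -3.55, SE 0.24, adjusted p = 1.15e-05), TYMS fell by 1.52 on the log2 scale (SE 0.15, adjusted p = 0.000504), and ZDHHC17 fell by 1.09 (adjusted p = 0.0184). CRIM1 rose from 27.5 ± 3.21 to 67.2 ± 20.8 CPM (log2 fold change 1.29, adjusted p = 0.0352), and PPP1R3F and IFI27L2 rose by 0.92 and 0.89 (adjusted p = 0.0298 and 0.0155). In all, 25 genes were called, 10 higher and 15 lower, and 54 with replicate number as a block. A blocked fit to these 6 libraries alone, chosen after the 54 was seen, called 121, and both blocked fits called all 25. SOX11, named only from the noradrenergic list, fell by 3.49 on the log2 scale (adjusted p = 7.79e-05). Without control replicate 2 the count was 9, without control replicate 3 it was 11, without combined replicate 3 it was 11, in a fit to these 6 libraries alone it was 9, and by DESeq2 it was 135. Of the 6 named genes other than ADARB1 and SRSF9, LNPEP and TYMS kept their calls in every fit that left out 1 library.

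Among the 39 interferon-stimulated genes, 0 were called over all genes in the combined group against control, 13 lay at an unadjusted p under 0.05, DESeq2 called 4 and limma-voom 0. Adjusted over the list alone, 12 were past the threshold, all of them lower in the combined group. IFIT2 went from 7.61 ± 2.18 to 1.99 ± 0.819 CPM (log2 fold change -1.92), IFIT3 from 7.69 ± 5.46 to 1.81 ± 0.316 CPM (-2.09), and IFIT1 from 14.4 ± 6.35 to 6.42 ± 1.54 CPM (-1.16). IFI6 went from 17.8 ± 9.71 to 8.28 ± 1.64 CPM (-1.11), with 8.14 CPM in ADAR2 OE and 9.73 CPM in SRSF9 KD. With the replicate block 9 were past it, without IFI44, IFITM2 and PSMB9. The list had a median of -0.24, and camera gave adjusted p = 1.1e-07, with adjusted p = 0.49 with an estimated correlation. Fry's test for change in either direction gave adjusted p = 0.0054, and its test for change in 1 direction gave 0.31. Of 9 epithelial markers, EPCAM (log2 fold change 1.24) and CLDN3 (1.30) were past the threshold adjusted over the list alone (0 called by edgeR over all genes, 2 by DESeq2; camera adjusted p = 0.00039, and adjusted p = 0.49 with an estimated correlation). Among 24 endoplasmic reticulum chaperones, DNAJB11 (0.43) was past it over the list alone (adjusted p = 0.0024, and adjusted p = 0.66 with an estimated correlation). Camera called 8 of the 24 lists, and 0 held with an estimated correlation or by fry's test for change in 1 direction. For change in either direction fry called 5 of the 8, the interferon, editing enzyme, SR protein, epithelial and neuronal lists. The editing enzyme and SR protein lists hold ADARB1 and SRSF9, altered by design, so their calls do not show a change of the other members.

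**Figure D4:**
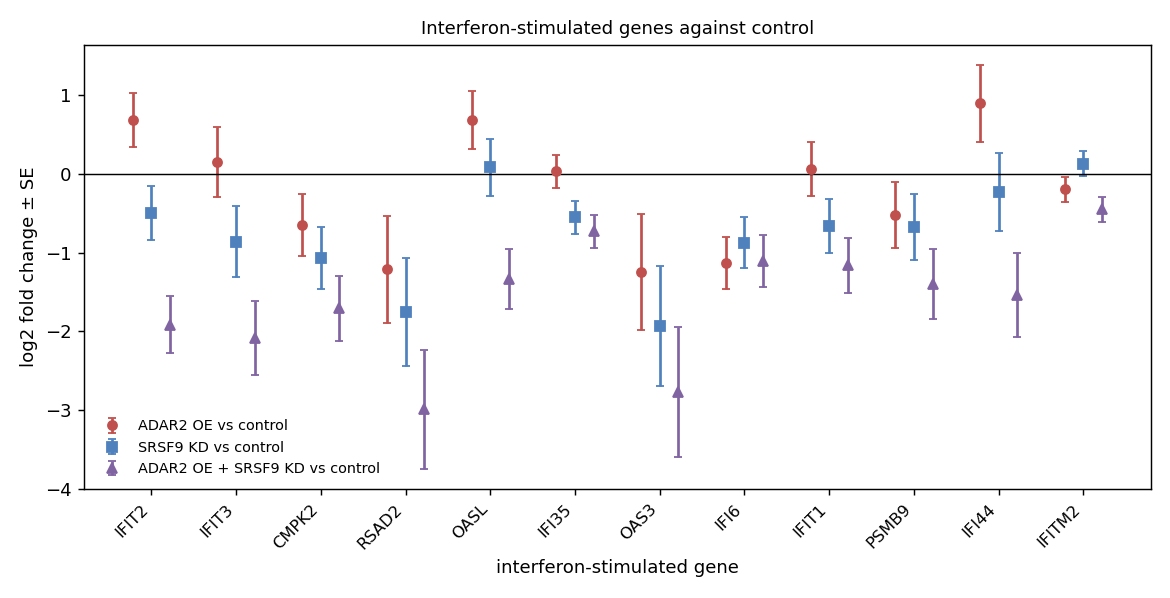
Log2 fold change against control, with its SE, of the 12 interferon-stimulated genes past the threshold over the list alone in the combined group, for ADAR2 OE, SRSF9 KD and the combined group. All 12 triangles of the combined group lie below 0, from -0.45 (IFITM2) to -2.99 (RSAD2), and IFIT2 lies at 0.69 in ADAR2 OE and -1.92 in the combined group. RSAD2 stood at 0.86 ± 0.791 CPM in control, and its control and combined libraries overlap.

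The interaction asked whether the SRSF9 knockdown effect differed with and without extra ADAR2. LNPEP had the largest positive interaction among the rule genes, 2.93 on the log2 scale (SE 0.32, adjusted p = 0.00157). It stood at 222 CPM in control and between 19 and 28.1 CPM in the other groups. ABCA3 had a log2 interaction of -3.25 (SE 0.32, adjusted p = 0.00109), being high in ADAR2 OE alone, and ZNF687 one of -2.23 (SE 0.20, adjusted p = 0.000739), being high in SRSF9 KD alone. RP11-347C12.2 and RP11-345J4.8, pseudogene copies of the kinase gene SMG1, had values of 1.44 and 1.39 (adjusted p = 0.00391 and 0.00586). In all, 11 genes were called, 4 with a positive and 7 with a negative value. The other genes of this count, chosen after their values were seen, were NALCN (3.87), ASNSP1 (-3.06), STXBP6 (-4.08), RNU6-611P (-4.38), APOBEC3G (-4.66) and POF1B (-6.22). SLC7A11 had an interaction of -1.55 with adjusted p = 0.0747 over all genes and 0.00155 over the integrated stress list alone, of which edgeR called 0 and DESeq2 1. Among 39 interferon-stimulated genes, IFIT2 (-2.11) and OASL (-2.10) were past the threshold over the list alone and 0 over all genes (4 at an unadjusted p under 0.05, 2 by DESeq2). All 78 ribosomal protein genes had positive values, with a median of 0.24 and 0 called (3 at an unadjusted p under 0.05, 0 by DESeq2; camera adjusted p = 6.6e-13, and adjusted p = 0.62 with an estimated correlation). Camera called 11 of the 24 lists, and 0 held with an estimated correlation or by fry's test for change in 1 direction or in either direction. All 5 rule genes kept their calls in the 12 fits that left out 1 library, and DESeq2 called 41 genes.

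Comparisons that share no library show which effects were seen in both settings. ADARB1 and MEIOB were the only genes higher both in ADAR2 OE against control and in the combined group against SRSF9 KD, where independent lists of these sizes would share 0.0015. ADARB1 was altered by design in both comparisons, so MEIOB alone bears on effects beyond the target. No gene (0) was lower in both, with 9 and 5 called lower by edgeR. Across the 23824 tested genes, which are not independent replicates, the log2 fold changes of these comparisons had a Pearson correlation of -0.077 and a Spearman correlation of -0.186. Over the 11355 genes with an average log2 CPM of at least 3 these were -0.194 and -0.349. The high immediate early side of the first component held 2 libraries of ADAR2 OE, 2 of SRSF9 KD, 1 of control and 1 of the combined group. This imbalance enters the comparisons of each correlation here, and of the knockdown below, with opposite signs. The negative values therefore do not show a reversed ADAR2 effect, and the weight of the imbalance was not tested. For the SRSF9 knockdown, IFI27L2 was higher, and SRSF9, TYMS and SOX11 were lower, both with and without extra ADAR2. Independent lists would share 0.0039 and 0.02 genes. SRSF9 was altered by design in both comparisons, so only IFI27L2, TYMS and SOX11 bear on effects beyond the target. The correlation across genes was 0.144 (Pearson) and 0.106 (Spearman), and 0.208 and 0.145 over the 11355 genes. This overlap of 4 became 31 by DESeq2, 2 in fits to only the groups compared, and 2 without ADAR2 OE replicate 2 or without combined replicate 3. SOX11 was not particular to the knockdown. It stood at 19.9 CPM in control and 7.33 CPM in ADAR2 OE (log2 fold change -1.44). By edgeR its adjusted p there was 0.118 over all genes and 0.00233 over the noradrenergic list alone. Its interaction was 1.78 (adjusted p = 0.396 over all genes and 0.00907 over that list alone).

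Comparisons with the same control libraries shared more. All 9 genes lower in ADAR2 OE than in control were also lower in SRSF9 KD and in the combined group, among them LNPEP, ZDHHC17, NDUFS7, RP11-345J4.8 and RP11-347C12.2. LNPEP stood at 28.1 ± 8.86 CPM in ADAR2 OE, 19.6 ± 3.02 CPM in SRSF9 KD and 19 ± 2.51 CPM in the combined group (SD, n = 3). NDUFS7 stood at 99.7 ± 9.36 CPM in control and at 59.2 ± 1.81, 61.4 ± 1.51 and 61.7 ± 6.78 CPM in the altered groups. SYT1 was higher in all 3 altered groups, with calls kept in 4 (ADAR2 OE), 1 (SRSF9 KD) and 2 (combined) of 6 fits without 1 library. In the combined group it was lost without control replicate 2 (adjusted p = 0.154), control replicate 3 (0.184), combined replicate 2 (0.059) or combined replicate 3 (0.164). Lists that share control libraries are not independent, and no reference was made for the number of genes they share. The shared genes are also not told apart from an effect of the manipulation itself. In 20 simulations with no change and the same control libraries, at most 1 gene was called in a comparison. Across genes the covariance of the log2 fold changes of ADAR2 OE and SRSF9 KD was 0.102, against a simulated mean of 0.0676 (range 0.0639 to 0.0703), and their correlation was 0.499, against a simulated mean of 0.476 (range 0.456 to 0.493). The simulated groups were drawn gene by gene, without variance common to many genes such as the first component. Its high immediate early side held 2 libraries each of ADAR2 OE and SRSF9 KD and 1 of control. Values above the simulated range therefore do not show a shared effect. With 3 controls the control libraries were not divided between the comparisons.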

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

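Of the tests in this part, those of library depth, of the replicate 3 libraries, of libraries left out, of low counts and of the parent gene SMG1 were chosen only after the result was seen.

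The effect of the SRSF9 knockdown differed between cells with and without extra ADAR2 in 11 genes, by a test of that difference. The differences on the log2 scale were 3.87 for NALCN, 2.93 for LNPEP, 1.44 for RP11-347C12.2, 1.39 for RP11-345J4.8, -2.23 for ZNF687, -3.06 for ASNSP1, -3.25 for ABCA3, -4.08 for STXBP6, -4.38 for RNU6-611P, -4.66 for APOBEC3G and -6.22 for POF1B. Of 100 drawn relabelings of the knockdown within each ADAR2 level, 5 gave as many genes, the real one included, so chance was not excluded for the count of 11. The highest other relabeling called 6476 genes. It and those with 2569 and 1049 genes set combined replicate 2 and ADAR2 OE replicates 1 and 2 against combined replicates 1 and 3 and ADAR2 OE replicate 3, as the level of immediate early genes does, which points to a structure of the samples.

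Of 79 genes that differed between any groups, 49 set 1 group apart from the other 3 by their group means, as ABCA3 (ADAR2 OE), ZNF687 (SRSF9 KD), CRIM1 (combined) and LNPEP (control) did, or 62% against 60.9% for 4 unrelated group means. With genes and their group chosen in 8 libraries and scored on the 4 left out, the left-out library of the group lay beyond the other 3 in the same direction in 100% of 44 choices over 22 of the 49 genes (25% by chance), which argues against a single library for these 22. CRIM1 was not among them. Its 3 combined libraries (45.7 to 87.2 CPM) all lay above the highest of the other 9 (32.6 CPM), an outcome that the choice of genes had favoured. Its call was kept in 1 of 6 fits without 1 library, both against ADAR2 OE and against control. For CRIM1 and the other genes not chosen, the part of a single library stays open. Noise at low counts did not account for all of it, since 40.8% of the 49 genes had at least 8 CPM in their highest group. A candidate explanation that stays open is that the groups were separately derived cell populations, which could each carry differences of their own; neither this nor a joint action of ADAR2 and SRSF9 was tested, and the labels do not say how the cells were made.

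Immediate early genes split the libraries within groups, from 864 to 2553 summed CPM, and this split went with the largest source of variance. The tables argue against library depth as the whole cause, since the library with the highest sum was the shallowest in 2 of 4 groups and the deepest in 1. A separate processing of the replicate 3 libraries may be a source of their own low sums, which were the lowest in 4 of 4 groups (864 to 956 CPM), but not of the whole split, since 3 of the 8 other libraries lay at or below 1.5 times their highest value. GC content and transcript length explained 2.7% of the variance of the gene loadings on the first component, with values for 95.9% of genes. Differences in handling or harvest may remain as a source; no biological explanation was tested, because the design names none within a group.

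RP11-345J4.8 and RP11-347C12.2, listed in the newer name table as SMG1P2 and SMG1P5, were called lower in all 3 altered groups than in control, as was a further copy of SMG1, RP11-645C24.2. Of 2 more copies, each called in SRSF9 KD alone, SMG1P1 had adjusted p = 0.174, 0.0277 and 0.074 and CTD-2547E10.2 had 0.238, 0.0488 and 0.0536 in ADAR2 OE, SRSF9 KD and the combined group; the median log2 fold changes of the 5 were -1.33, -1.31 and -1.28. A change of the parent gene SMG1 read through its copies does not account for this, since such reads lower a copy by no more than SMG1 fell: SMG1 had 0.07, -0.21 and -0.32 (SE 0.20) and fell by less than each copy in 3 of 3 comparisons, by at least 3.7, 3.1 and 2.9 standard errors of the difference. Reads shared between copies may explain why RP11-345J4.8 and RP11-347C12.2 moved as 1. Their counts over the 12 libraries lay near a constant ratio, with a chi-square of 0.513 per degree of freedom, in 1 pair of the 10. The other 9 pairs ran from 2.44 to 23.9. Independent reads in constant ratio give 1 on average and can give less. Counting both ends of a read pair, which was probable here, would raise that average. This pair is the lowest of 10, so sharing stays open. Sharing alone would not lower the copies, and a change of the copies themselves stays open, untested.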

How the results depend on the processing

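The fit with 1 surrogate variable and the blocked fit to the combined and control libraries alone were chosen only after the result was seen; the other alternatives were planned. ADARB1 and SRSF9 kept their side of the threshold in all 120 alternatives. Of 2211 alternatives for 148 other named results, 1699 kept theirs. Another 500 lost the call (399 of them in fits without 1 library, which test fewer samples), and 12 gained it. The sign turned in 0 alternatives where the main fit or the alternative made a call. Turns of sign between fits that both made no call were not counted. Counts are given below in the order ADAR2 OE with control, SRSF9 KD with control, combined with ADAR2 OE, combined with SRSF9 KD, combined with control, and interaction, against 21, 50, 22, 8, 25 and 11. Within 1.5 times these counts lay RLE scaling, library totals alone, limma-voom, a term for replicate 3 and a log2 minimum of 1, in all 6 comparisons. The fewest simulated 2-fold changes were recovered in the interaction, 26.9%.

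DESeq2 gave 51, 188, 162, 15, 135 and 41. No low-count filter gave 34, 89, 56, 13, 53 and 22, and at least 5 CPM in 3 libraries, with fewer genes tested, gave 10, 24, 14, 3, 16 and 7. The replicate block gave 28, 98, 44, 12, 54 and 20, and in a fit to the combined and control libraries alone 121; in that comparison it changed no call of a named gene and no call by camera. In the others the numbers were not taken as pairs, since each had at least 1 pair under 0.1 (lowest -0.15, 0.05, -0.2 and 0.09); 12 of all 18 pairs were above it, and 11 of 12 libraries correlated best with their own number. Fits to only the groups compared gave 17, 44, 8, 7 and 9, without the interaction, which needs all groups. The surrogate variable gave 51, 365, 800, 16, 342 and 33. Without 1 library the ranges were 13 to 18, 18 to 29, 7 to 21, 6 to 8, 9 to 27, and 8 to 12. The 4 genes of the knockdown effect shared with and without ADAR2 became 31 with DESeq2, 10 with no filter, 13 with the block, 2 with only the groups compared and 103 with the surrogate variable, and 2 to 4 without 1 library. The 2 genes of the ADAR2 effect stayed at 2. In the main fit these overlaps include SRSF9 and ADARB1, which were altered by design. For the changes in all these counts the cause was not tested.

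Of the list results called by camera, 52 of 52 were lost with an estimated correlation and 52 of 52 with fry's test for change in 1 direction. Fry's test for change in either direction, which asks a different question, called 11 of the 52. Among these 11 are editing enzyme lists, which hold ADARB1, and SR protein lists, which hold SRSF9. Both genes were altered by design, so those calls do not show a change of the other members. The cell cycle list, called in SRSF9 KD with control, had TYMS alone past the threshold adjusted over the list alone. Histones turned direction in ADAR2 OE with control at 5 CPM (adjusted p = 0.96) and without replicate 2 (0.32), in the combined group with ADAR2 OE without replicate 2 (0.38), and in the interaction at 5 CPM (0.83) and without replicate 2 (0.15). Without replicate 2, glycolysis and hypoxia genes turned direction in ADAR2 OE with control (0.043), as did ribosomal proteins in the combined group with ADAR2 OE (0.58). Without 1 replicate number, histones ran from 3.3e-11 to 0.32, from 1.5e-05 to 0.38 and from 1.3e-11 to 0.16 in these comparisons, glycolysis and hypoxia genes from 4e-05 to 0.043, and ribosomal proteins from 3.4e-14 to 0.58. The cause was not tested.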

Other observations

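The sorting of genes by the groups that stood apart, the sums of lists by the sides of the first component and the count of splits that part all pairs were chosen only after the result was seen.

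By their group means, 27 of the 79 genes that differed between any groups set SRSF9 KD and the combined group apart from control and ADAR2 OE, SRSF9 itself among them. The knockdown effect was called by edgeR both with and without extra ADAR2 in only 4 of these, SRSF9, TYMS, SOX11 and IFI27L2. RP6-99M1.2, TCEAL3, LRIG3 and SFXN1 were called in the combined group with ADAR2 OE but not in SRSF9 KD with control. The others did not pass in the combined group with ADAR2 OE, among them the rule genes CHUK, BTBD1, SDC2, UBR7, ZHX1, OGDHL and PPP1R3F. COL27A1, MDC1, SETD7, GPR180, RAB40B and PAX7 did not pass there either. COL27A1, GPR180 and RAB40B also did not pass in SRSF9 KD with control. COL27A1, a fibrillar collagen gene, stood at 60.8 and 49.6 CPM in control and ADAR2 OE and at 83.9 and 73.2 CPM in SRSF9 KD and the combined group (adjusted p = 0.0229 for any difference between the 4 groups by edgeR quasi-likelihood, and 0.179 for SRSF9 KD with control). MDC1, a mediator of the DNA damage checkpoint, stood at 178 and 180 CPM without the knockdown and at 116 and 121 CPM with it, and SETD7, a lysine methyltransferase, at 126 and 135 CPM and at 74.3 and 86 CPM. GPR180, RAB40B and PAX7 were further members, chosen like the other genes here that the rule did not name after their values were seen. PAX7, a transcription factor of the neural crest and muscle lineages, stood at 0.962 and 1.99 CPM without the knockdown and at 4.47 and 3.49 CPM with it. In SRSF9 KD with control, PAX7 lost its call without control replicate 1 (adjusted p = 0.0558), control replicate 2 (0.0748) or SRSF9 KD replicate 3 (0.0549). MDC1 and SETD7 lost theirs in all 6 such fits: without control replicates 1, 2 and 3 they had 0.0536, 0.116 and 0.119 (MDC1) and 0.125, 0.156 and 0.101 (SETD7), and without SRSF9 KD replicates 1, 2 and 3 they had 0.157, 0.115 and 0.0526 (MDC1) and 0.223, 0.114 and 0.116 (SETD7). LGALS3BP, a secreted glycoprotein, was instead highest in SRSF9 KD, at 64.3 CPM against 37.7 in control, 26.4 in ADAR2 OE and 30.1 in the combined group.

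Several gene lists had 0 members called by edgeR in ADAR2 OE with control, and are given here for that comparison with the median log2 fold change and the p with an estimated correlation. Kinases and importers of SR proteins had a median of 0.06 (adjusted p = 0.8), p53 targets -0.05 (0.8), endoplasmic reticulum chaperones 0.06 (0.8), heat shock proteins -0.22 (0.8), histones -0.12 (0.8), glial markers 0.10 (0.8), and mitochondrial mRNAs -0.09 (0.8). At the preset correlation camera called histones lower (adjusted p = 0.014), a direction that turned in some alternatives, as given above. Small nuclear and nucleolar host transcripts had a median of -0.09 (0.8), double-stranded RNA sensors -0.05 (0.97) and immediate early genes -0.05 (0.97). The summed CPM of glial markers and of host transcripts followed the sides of the first component, at 43 to 72 and 1804 to 2520 on the high immediate early side (2 libraries of ADAR2 OE, 1 of control) and at 25 to 40 and 1212 to 1521 on the other. At an unadjusted p under 0.05 there were 4 histones and 1 gene each among p53 targets, glial markers, host transcripts and double-stranded RNA sensors, with 0 in the other lists of this paragraph, and DESeq2 and limma-voom called 0 in all of them.

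The counts of genes called between groups of 3 were set against the other splits of the same 6 libraries. With 10 splits the smallest possible share is 0.1, so these splits are too few for a share under 0.05. In ADAR2 OE with control the real split called 21 genes and the highest other 0, so that 1 of 10 gave as many. In SRSF9 KD with control it called 50 and the highest other 0 (1 of 10), in the combined group with ADAR2 OE 22 and 1 (1 of 10), and in the combined group with control 25 and 1 (1 of 10). In this last comparison, where the replicate numbers were taken as pairs, 4 splits part all 3 pairs, and the highest other of these called 0; the others keep at least 1 pair together, and the highest of them called 1. In the combined group with SRSF9 KD the real split called 8 and the highest other 2270 (2 of 10). That split set combined replicates 1 and 3 with SRSF9 KD replicate 3 against combined replicate 2 with SRSF9 KD replicates 1 and 2, which follows the immediate early level and points to a structure of the samples. Part of the genes shared between comparisons with control, 9 lower in all 3 altered groups, may come from the shared control libraries, and how large a part was not tested. Across all tested genes most of the correlation with control in common was there in the simulations too, 0.476 on average against 0.499.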
